A study of Trichoderma reesei with 6 samples.

How the data were processed

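The series holds RNA-seq libraries from mycelia of 2 Trichoderma reesei strains, the wild type QM9414 and a cre1 deletion mutant, with 3 libraries each, all cultured with 1 mM sophorose. RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and column headers of the tables were matched to samples through the accession lines at the head of each file.

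The raw table holds whole-number read counts per protein ID, as deposited by the authors, with 1 column per library and no normalization. Alignment with Bowtie 0.12.8, SAMtools 0.1.18 and DESeq 1.10.1 are named in the submitters' processing notes. The genome build, the gene annotation, the counting tool and the strand setting are not given in the sources used here, so reads shared by near-identical or overlapping genes may have been counted in ways that cannot be traced, and antisense reads were not told apart. A second deposited table holds a signal per protein ID that is never negative, which was checked to equal the raw count divided by 1 size factor per library (0.798, 1.04 and 1.13 for wild-type replicates 1 to 3 and 1.35, 0.706 and 1.13 for mutant replicates 1 to 3). It was used for checks only. The third table holds the authors' own log2 fold change and adjusted p-value for each protein ID, per the file headers. The log2 fold change equalled the log2 ratio of the group means of normalized counts, mutant over wild type, within 0.001 for 8741 of 8741 IDs above 0 in both groups. It is set to 100 for 54 IDs with the wild type at 0 and to -100 for 129 IDs with the mutant at 0. The adjustment method of that p-value is not given in the sources used here.

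Of 9129 protein IDs, 9072 matched a locus tag of the form TRIREDRAFT_ID in a table of RefSeq genes for the strain QM6a (assembly v2.0), 57 did not, 226 had a gene symbol there, and 205 had no count in any library. No genome sequence was used, and the reference table served only for names and for which genes neighbour each other. Genes without a symbol are given by locus tag.

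Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. IDs with low counts were removed by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a negative binomial model with strain as its term was fitted with glmQLFit (robust) and tested two-sided with glmQLFTest. Benjamini-Hochberg adjustment ran over the 8190 genes tested, with a threshold of 0.05. Adjusted p-values of single genes come from this test unless another is named. Standard errors are the fitted log2 fold change over the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. The TMM factors were 1.11, 1.10 and 1.06 for wild-type replicates 1 to 3 and 1.13, 0.71 and 0.956 for mutant replicates 1 to 3, and the common biological coefficient of variation was 0.116. The labels describe biological replicates without naming separate cultures, and the p-values measure the spread between these samples. A count of 0 in a library allows up to 3 counts, which is 0.138 to 0.229 CPM at these depths, for counting error only. No library pair had counts within sampling noise of each other (chi-square per degree of freedom of at least 17.2).

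The groups, tests, alternatives, gene lists by locus and the rule for naming genes were chosen before the data were examined. Lists by locus were cellulases and accessory proteins, beta-glucosidases, hemicellulases, regulators and sugar transporters. Of their 58 members 20 carry a symbol in the reference, which was the name assumed beforehand for 19 and another name for 1. The identity of the other members was assumed by locus and not checked. Further lists had been planned by words in gene product descriptions. The reference used here gives no such descriptions, so they were replaced, before any model was fitted, by lists built from the reference symbols: ribosomal proteins, proteasome subunits, chitinases and N-acetylglucosaminidases, glycolysis and pentose phosphate pathway, citrate, acetate and glyoxylate metabolism, pentose, galactose and galacturonate catabolism, protein folding and secretion, heterotrimeric G proteins and protein kinase A, MAP kinase pathway, photoreceptors and photolyase, histones, hydrophobins, small GTPases, CREB, CREC and SNF1 homologues, and the HAP complex. A planned list of conidial markers could not be built from symbols and was not analysed here. The 16 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the 16 lists, and also with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks only whether its own members move one way. With an estimated correlation no list was called (adjusted p = 0.999 for each). That setting was not tried on a planted list, so what change it could call with 3 libraries per strain is not known.

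Genes are named by the following rule. It takes all regulators, 1 of which is not reported here, up to 4 members past the threshold with the smallest p from each list by locus, and up to 3 such members from each further list with a set test or at least 2 members past the threshold. It also takes the 8 largest rises and 8 largest falls among genes past the threshold whose libraries do not overlap between strains and whose mean is at least 5 CPM in 1 strain, up to 3 per direction being without a symbol. Other genes named were chosen after their values were seen, as stated where they appear.

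On counts simulated from the real means, dispersions and library sizes, the fit recovered 65% of genes changed 1.5-fold, 88.3% of those changed 2-fold and 98.3% of those changed 4-fold over 8149 genes, with 14 false calls among 178. Camera called a planted list of 20 genes changed 2-fold and 0 of 20 random lists. The simulated genes varied independently, whereas the estimated correlation was 0.483 for the hemicellulases. This simulation therefore does not show how often camera with the preset correlation falsely calls lists of correlated genes. For the fit, 80 genes were changed 1.5-fold, 60 were changed 2-fold and 60 were changed 4-fold, far fewer than were called in the real data. Each unchanged gene had the same mean in all libraries. An excess of single IDs in 1 library was thus not simulated, and the recovery does not test the scaling under it. Alternatives were relative log expression and upper-quartile scaling, library totals alone, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma voom, non-robust fitting, a replicate block, each library left out in turn and, chosen after seeing the data, leaving out the 2 most abundant protein IDs. Neighbouring genes were tested in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3 by 10000 shuffles of the calls within 10 classes of mean CPM. In simulated data with 20 planted runs that test gave a share of shuffles of 0.001, the smallest that 1000 shuffles can give, and 0.318 for scattered genes. Counting intervals came from SciPy 1.17.1 and R, and figures from Matplotlib 3.10.9.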

Results

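RNA-seq read counts were analysed from mycelia of Trichoderma reesei, a filamentous fungus that secretes plant cell wall-degrading enzymes, cultured with 1 mM sophorose. Sophorose is a disaccharide of glucose that induces cellulase genes in this species. The wild-type strain QM9414 was compared with a mutant lacking cre1 (Δcre1), the gene of the carbon catabolite repressor CRE1, to find the genes whose transcript level depends on this regulator under the inducer. Each strain had 3 libraries, described in the series design as biological replicates. The design text names harvests at 2, 4 and 6 h, but no label ties a library to a harvest time. The counts summed to 13122470, 17402437 and 19557827 in wild-type replicates 1, 2 and 3 and to 21688837, 18196564 and 21778997 in mutant replicates 1, 2 and 3. Protein IDs 48266 and 61593, which have no entry in the reference used here, together took 3.0, 2.7 and 4.3% of the counts in the wild-type libraries and 6.1, 37.8 and 11.1% in the mutant libraries. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.991 to 0.993 within the wild type, 0.988 to 0.991 within the mutant and 0.932 to 0.946 between strains. The first principal component held 81.9% of the variance and separated the strains, and the next held 6.6%.

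The transcript of the deleted gene, cre1, was at 474, 502 and 452 CPM in the wild-type libraries and at 42.2, 45.2 and 61.8 CPM in the mutant libraries. It fell by 3.26 ± 0.14 (SE) on the log2 scale, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 2.02e-09. The mutant mean was 10.5% of the wild-type mean. The part of cre1 that the deletion removed is not given in the sources used here.

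Loss of cre1 was accompanied by changes in a large part of the transcriptome, and the strongest changes were mostly falls. Of 14 hemicellulase genes 11 rose and none fell. Camera called that set with a preset correlation (adjusted p = 0.000693) but not with an estimated one, which gave 0.999 for every list. Of 13 cellulases and accessory proteins 7 rose and 1 fell. Beta-glucosidases (1 rose, 2 fell), regulators (3 and 4) and sugar transporters (3 and 3) were more evenly divided. Of 8190 genes tested, 3762 changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1863 being higher and 1899 lower in the mutant. At least 2-fold changes were counted for 327 of the higher and 761 of the lower genes. All 3 mutant libraries lay above all 3 wild-type libraries for 2290 genes and below them for 2307, together 56.1% of the genes, where chance gives 10%. When libraries were scaled by their totals alone, 2018 genes changed and 19.8% of them were higher, against 49.5% with TMM, and the median log2 fold change of all genes was -0.215 against 0.014. That scaling counts the excess of the 2 abundant IDs against all other genes, and directions below are relative to the TMM scale.

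**Figure D1:**
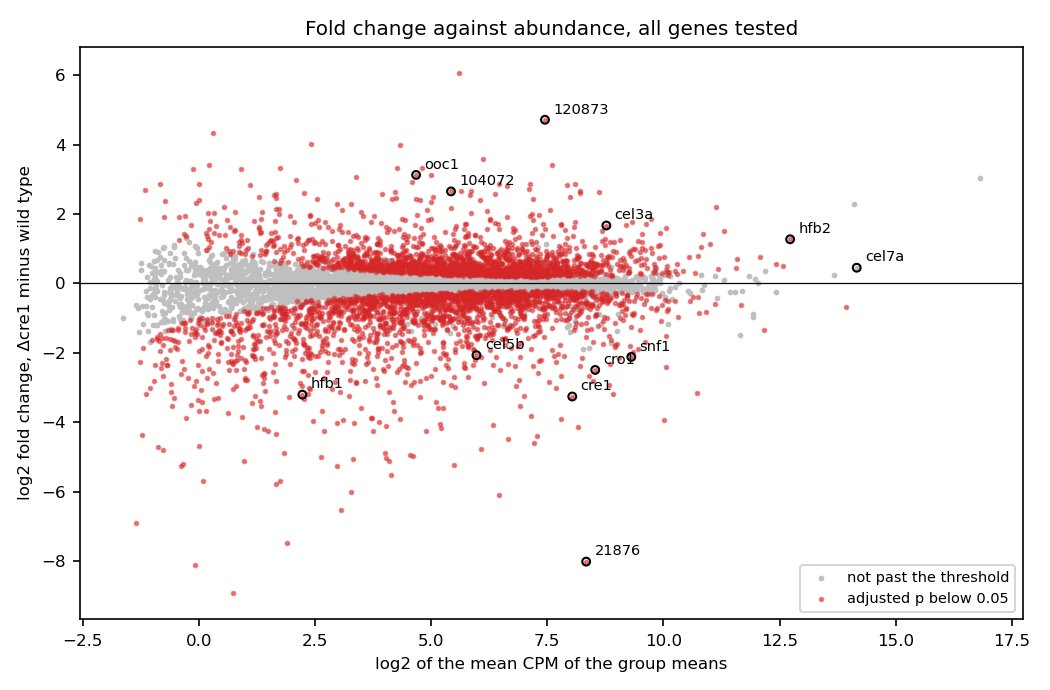
Log2 fold change of the mutant against the wild type (vertical axis) over the log2 of mean CPM (horizontal axis) for the 8190 genes tested, 3 libraries per strain; red points passed an adjusted p of 0.05 and circles mark genes named in the text, numbers being TRIREDRAFT locus tags. More red points lie beyond a 2-fold fall (761) than beyond a 2-fold rise (327).

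Among the genes with the largest rises, TRIREDRAFT_76682 went from 1.46 ± 0.83 to 95.7 ± 57.8 CPM (mean ± SD, n = 3), a log2 fold change of 6.06 ± 0.95 (SE). TRIREDRAFT_120873 rose from 12.8 ± 1.02 to 337 ± 17.9 CPM, by 4.72 ± 0.10 on the log2 scale. TRIREDRAFT_73256 rose by 4.01 ± 0.61, from a low level of 0.656 ± 0.338 to 10.0 ± 5.55 CPM, and ooc1 by 3.13 ± 0.36. The largest fall among genes of at least 5 CPM was that of TRIREDRAFT_21876, from 644 ± 90.4 to 2.56 ± 0.74 CPM, a log2 fold change of -8.01 ± 0.21. TRIREDRAFT_58366 fell by 6.52 ± 0.32, from 16.55 ± 1.03 to 0.214 ± 0.217 CPM, and cro1 by 2.49 ± 0.11 on the log2 scale. The mutant counts of TRIREDRAFT_58366 were 2, 6 and 2 in replicates 1, 2 and 3. The naming rule took at most 3 genes without a symbol per direction, so some changes larger than those of ooc1 and cro1 were passed over. Examples, chosen after their values were seen, were TRIREDRAFT_69692 at 3.57 ± 0.12 and TRIREDRAFT_104251 at -6.09 ± 0.17. TRIREDRAFT_56278 had 357 counts over the wild-type libraries and 2 over the mutant libraries, with a fitted log2 fold change of -7.46 ± 1.81. Its mutant level was 0.525% of the wild type, with an exact 95% counting interval of 0.0633 to 1.91% that leaves out the spread between libraries. Of these wild-type counts 244 came from replicate 1, and the adjusted p of 0.0285 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment became 0.11, 0.0966 or 0.181 without mutant replicate 1, 2 or 3. Both mutant counts of TRIREDRAFT_56278 came from replicate 3, so that no mutant count was left without that library. For the other genes of this group that test gave adjusted p-values from 8.58e-13 for TRIREDRAFT_120873 to 0.00821 for TRIREDRAFT_76682.

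Of 14 genes tested in the list of hemicellulases, enzymes that cleave xylan, mannan and their side chains, 11 rose and none fell. The same numbers passed when adjusted over the list alone. Of the 14, 2 carried a symbol in the reference, and the identity of the others was assumed by locus and not checked. The median log2 fold change was 1.20. TRIREDRAFT_111849 rose from 33.5 ± 2.15 to 121 ± 15.4 CPM (SD, n = 3), and TRIREDRAFT_55319 rose from 293 ± 41.2 to 996 ± 39.9 CPM. Their log2 fold changes were 1.85 ± 0.10 and 1.76 ± 0.11 (SE). The other 2 of the 4 members with the smallest p were TRIREDRAFT_72704 at 1.61 ± 0.13 and TRIREDRAFT_72632 at 1.18 ± 0.16. Further members are named after their values were seen. The highest log2 fold change of the list was 2.65, for TRIREDRAFT_123283, which was at 5.28 ± 1.95 CPM in the wild type. The 3 members that did not pass were TRIREDRAFT_121127, TRIREDRAFT_123818 and TRIREDRAFT_120229. Of these TRIREDRAFT_121127, the most abundant of the list in the wild type, was at 656.5 ± 63.8 CPM there and 613 ± 107 CPM in the mutant. The mannanase gene man5a rose by 1.22 ± 0.38, with an adjusted p of 0.0442 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That call was lost without wild-type replicate 2 or 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.135 and 0.0978) and without mutant replicate 1 or 3 (0.122 and 0.0903), and for man5a also with no low-count filter (0.0559). As a set the hemicellulases were higher than other genes by camera with a preset correlation of 0.01 (adjusted p = 0.000693 over 16 lists). That call was lost with an estimated correlation, which gave an adjusted p of 0.999 for every list. With the preset correlation it held without each single library (camera adjusted p of 9.15e-06 to 0.00323), and fry gave an adjusted p of 0.0142. With libraries scaled by totals alone, 8 of the 14 rose.

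The 13 cellulases and accessory proteins of cellulose breakdown held 7 members that rose and 1 that fell, with the same numbers when adjusted over the list alone and a median log2 fold change of 0.53. With library totals alone 6 rose and 1 fell. The cellulose-active oxidoreductase gene cel61a rose from 451 ± 21.0 to 1029 ± 161 CPM (SD, n = 3), and the endoglucanase gene cel7b from 615 ± 68.0 to 1324 ± 274 CPM. Their log2 fold changes were 1.19 ± 0.12 and 1.105 ± 0.148 (SE), and that of TRIREDRAFT_49976 was 1.01 ± 0.11. The endoglucanase gene cel5b went the other way, from 101 ± 4.90 to 24.3 ± 2.99 CPM, a log2 fold change of -2.07 ± 0.10. Adjusted p-values of these 4 genes ran from 1.69e-09 to 5.16e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The cellobiohydrolase gene cel7a, chosen after its values were seen because it was the most abundant transcript with a symbol, was at 15450 ± 1692 CPM in the wild type and 21170 ± 5739 CPM in the mutant. Its log2 fold change of 0.45 ± 0.20 did not pass the test (adjusted p = 0.0735 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but passed DESeq2's Wald test (adjusted p = 0.0124). The set was not called by camera (adjusted p = 0.0777). Without wild-type replicate 1 or mutant replicate 2 it was called (adjusted p = 0.023 and 0.00375), and over all alternatives the adjusted p ranged from 0.00375 to 0.999.

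**Figure D2:**
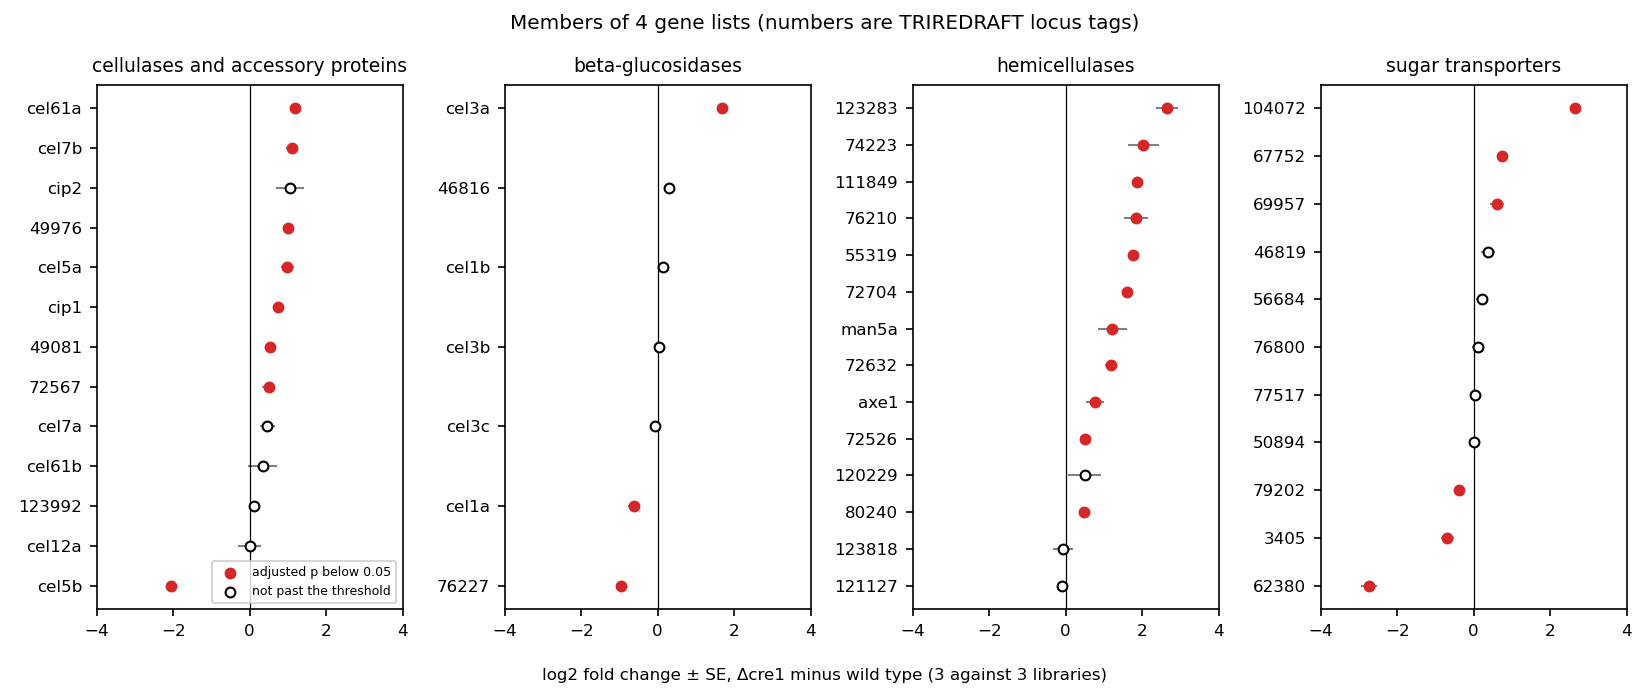
Log2 fold change of the mutant against the wild type for each tested member of 4 gene lists (points) with its standard error (bars, hidden where shorter than the point), 3 libraries per strain; filled points passed an adjusted p of 0.05 and numbers are TRIREDRAFT locus tags. Of the hemicellulases 11 of 14 rose, and the other 3 lists held members on both sides of 0 that passed.

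Of 7 beta-glucosidases, which release glucose from cellobiose and sophorose, 1 rose and 2 fell, also when adjusted over the list alone. The gene that rose was cel3a, from 209 ± 10.4 to 665 ± 136 CPM (SD, n = 3), a log2 fold change of 1.67 ± 0.13 (SE). TRIREDRAFT_76227 fell by 0.95 ± 0.08 and cel1a by 0.63 ± 0.14 on the log2 scale. The 3 adjusted p-values lay between 2.32e-07 and 0.00228 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median was 0.03 and camera did not call the set (adjusted p = 0.999).

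Of 11 regulators of cellulase, nitrogen and pH-responsive genes, cre1 included, 3 rose and 4 fell, also when adjusted over the list alone. TRIREDRAFT_41617 rose from 13.3 ± 1.89 to 47.5 ± 4.14 CPM (SD, n = 3), a log2 fold change of 1.83 ± 0.13 (SE). TRIREDRAFT_54675 rose by 0.39 ± 0.08, whereas the repressor gene ace1 fell by 0.43 ± 0.10, TRIREDRAFT_76817 by 0.32 ± 0.10 and TRIREDRAFT_77513 by 0.29 ± 0.10 on the log2 scale. The calls of TRIREDRAFT_54675 and TRIREDRAFT_77513 were lost with library totals alone, where 1 regulator rose and 3 fell. There the rise of TRIREDRAFT_54675 shrank to 0.16 ± 0.22, whereas the fall of TRIREDRAFT_77513 grew to -0.52 ± 0.21 with a larger SE. Adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 4.52e-08 for TRIREDRAFT_41617, 0.00351 for ace1, 0.0211 for TRIREDRAFT_76817 and 0.0306 for TRIREDRAFT_77513. In the same test the last was lost without wild-type replicate 2 (edgeR adjusted p = 0.123) or mutant replicate 2 (0.139), and that of TRIREDRAFT_76817 without wild-type replicate 2 (0.0815), mutant replicate 1 (0.0641) or mutant replicate 2 (0.0796). The gene of the main cellulase and xylanase activator, xyr1, was at 3014 ± 332 CPM in the wild type and 2522 ± 565 CPM in the mutant, a log2 fold change of -0.26 ± 0.16 that did not pass (adjusted p = 0.205 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without single libraries the value for xyr1 ranged from -0.10 without mutant replicate 1 (edgeR adjusted p = 0.594) to -0.44 without mutant replicate 3 (0.035), the only such fit in which it passed. TRIREDRAFT_26163, TRIREDRAFT_52368 and TRIREDRAFT_120698 did not pass, at log2 fold changes of 0.03 ± 0.13, -0.08 ± 0.10 and -0.17 ± 0.10. The set was not called by camera (adjusted p = 0.834), and the 10 members other than cre1 gave an unadjusted p of 0.91.

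Of 11 sugar transporters, 3 rose and 3 fell, also when adjusted over the list alone, against 1 and 3 with library totals alone. Of these 11, 0 carried a symbol in the reference, so that their identity was assumed by locus and not checked. TRIREDRAFT_104072 rose from 11.8 ± 1.92 to 74.2 ± 3.13 CPM (SD, n = 3), a log2 fold change of 2.65 ± 0.12 (SE), and TRIREDRAFT_67752 rose by 0.75 ± 0.11, the latter call being lost with library totals alone (0.52 ± 0.24). TRIREDRAFT_62380 fell from 51.7 ± 2.34 to 7.62 ± 2.89 CPM, by 2.74 ± 0.21 on the log2 scale. TRIREDRAFT_3405, the most abundant member of the list in both strains, fell from 19370 ± 2000 to 12050 ± 1213 CPM, a log2 fold change of -0.69 ± 0.16. Adjusted p-values of the 4 genes lay between 6.96e-10 and 0.00293 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the set was not called by camera (adjusted p = 0.834).

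**Figure D3:**
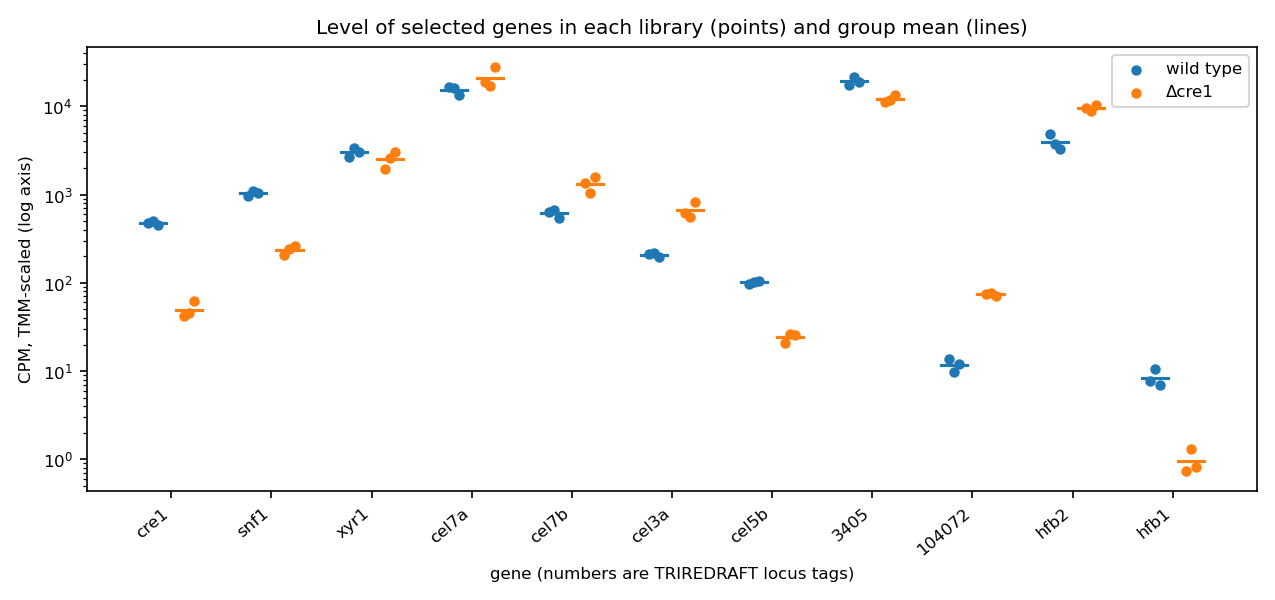
TMM-scaled CPM (vertical log axis) of 11 genes in each of the 3 wild-type (blue) and 3 Δcre1 (orange) libraries as points, with group means as lines; numbers on the horizontal axis are TRIREDRAFT locus tags. The mutant libraries lie below the wild type for cre1 (42.2 to 61.8 against 452 to 502 CPM) and above it for cel3a and hfb2.

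Genes of central carbon metabolism included several that fell. Of 7 genes of glycolysis and the pentose phosphate pathway none rose and 4 fell, also when adjusted over the list alone, and pgk1 (phosphoglycerate kinase), gpd1 (glyceraldehyde-phosphate dehydrogenase) and eno1 (enolase) fell by 1.23 ± 0.10, 1.08 ± 0.11 and 0.63 ± 0.11 (SE) on the log2 scale. The set was not called by camera (adjusted p = 0.285), while fry, which asks only whether members move one way, gave an adjusted p of 0.0142. Of 9 genes of pentose, galactose and galacturonate breakdown 3 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.834). Here the L-xylulose reductase-named gene lxr1 went from 122 ± 26.6 to 32.8 ± 6.23 CPM (SD, n = 3), a log2 fold change of -1.90 ± 0.20, whereas gld1 rose by 1.05 ± 0.20 and lad1, for arabinitol dehydrogenase, by 0.76 ± 0.13. Of 7 genes of citrate, acetate and glyoxylate metabolism 1 rose and 2 fell, against 1 and 3 when adjusted over the list alone (camera adjusted p = 0.936). These were acu9, up by 0.65 ± 0.10, and idh2 and acl2, at -0.34 ± 0.11 and -0.31 ± 0.10. Calls of acu9, lad1 and idh2 were lost with library totals alone, where 1 pentose gene rose and 2 fell and 1 citrate gene fell. The rises of acu9 and lad1 shrank there to 0.43 ± 0.22 and 0.55 ± 0.28, whereas the fall of idh2 grew to -0.58 ± 0.24 with a larger SE. Leaving out any single library except mutant replicate 3 ended the call of idh2 (edgeR adjusted p of 0.0622 to 0.0921), and leaving out wild-type replicate 2 or 3 or mutant replicate 1 ended that of acl2 (adjusted p = 0.126, 0.0958 and 0.0692).

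Among signalling genes in the lists the largest change was that of snf1, which bears the name of the kinase that acts in glucose derepression in yeast. It fell from 1030 ± 61.7 to 238 ± 29.0 CPM (SD, n = 3), a log2 fold change of -2.12 ± 0.11 (SE), with an adjusted p of 2.88e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In its list of 3 genes creb fell by 0.32 ± 0.08 and 1 did not pass, and the counts were equal when adjusted over the list alone. Of 8 small GTPases 5 rose and none fell, also when adjusted over the list alone, with rsr1 at 0.96 ± 0.09, cdc42 at 0.66 ± 0.08 and rac1 at 0.43 ± 0.08, but only 1 of the 8 rose with library totals alone. The small GTPases were not called by camera (adjusted p = 0.14) and had an adjusted p of 0.00197 by fry. Of 9 genes of heterotrimeric G proteins and protein kinase A 3 rose and 1 fell (4 and 1 when adjusted over the list alone), among them gna1 at 0.49 ± 0.08, tgb1 at 0.24 ± 0.08 and gna3 at -0.38 ± 0.09, and none passed with library totals alone, at 0.26 ± 0.22 for gna1, 0.00 ± 0.23 for tgb1 and a larger fall of -0.61 ± 0.25 for gna3 (camera adjusted p = 0.692 in the TMM fit). The call of tgb1 was lost without wild-type replicate 3, mutant replicate 2 or mutant replicate 3 (edgeR adjusted p = 0.0948, 0.115 and 0.061). Of 5 MAP kinase pathway genes tmk3 fell, at -0.35 ± 0.10, and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.999), and without wild-type replicate 2 or mutant replicate 2 tmk3 had edgeR adjusted p-values of 0.0606 and 0.0586. In the HAP complex list hap3 rose by 0.34 ± 0.09 and hap2 fell by 0.28 ± 0.11, also when adjusted over the list alone. Both calls were lost with library totals alone, where hap3 shrank to 0.12 ± 0.24 and the fall of hap2 grew to -0.53 ± 0.24 with a larger SE, and that of hap2 was lost without any single library except mutant replicate 3 (edgeR adjusted p of 0.0531 to 0.196). The call of hap2, at an adjusted p of 0.0499 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was also lost with DESeq2 (0.068), limma voom (0.0561), non-robust fitting (0.0627) and no low-count filter (0.0502).

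Cell wall and secretion genes held members that rose and members that fell. All 3 hydrophobins, small secreted surface proteins, changed, also when adjusted over the list alone, with a median log2 fold change of 1.05 and a mean of -0.29. Of these hfb2 rose from 3966 ± 772 to 9591 ± 750 CPM (SD, n = 3) and hfb3 from 1166 ± 114 to 2418 ± 63.8 CPM, log2 fold changes of 1.27 ± 0.16 and 1.05 ± 0.11 (SE). The low-abundance hfb1 fell from 8.41 ± 1.88 to 0.956 ± 0.315 CPM, a log2 fold change of -3.20 ± 0.27. Of 15 chitinases and N-acetylglucosaminidases 7 rose and 2 fell, against 7 and 3 when adjusted over the list alone. They included chit18-11 at 1.86 ± 0.26, chi18-rel1 at 1.62 ± 0.09, chi18-7 at -1.20 ± 0.10 and chi18-2 at -2.62 ± 0.38, and with library totals alone 3 rose and 3 fell. That set had an adjusted p of 0.692 by camera and 0.0132 by fry, with a median of -0.01 and a mean of 0.19, so that median and test differed in sign. Of 13 protein folding and secretion genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.705, fry 0.0472). The disulfide isomerase gene pdi1 rose from 1120 ± 59.9 to 1886 ± 88.2 CPM, by 0.75 ± 0.11 on the log2 scale, and the unfolded protein sensor gene ire1 by 0.32 ± 0.10, neither of which passed with library totals alone (0.51 ± 0.22 and 0.09 ± 0.21), and snc1 fell by 0.62 ± 0.10. The call of ire1 was also lost without wild-type replicate 3 or mutant replicate 2 (edgeR adjusted p = 0.0543 and 0.0864).

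Lists of housekeeping genes held few members past the test. Of 42 ribosomal protein genes rpl38 fell, at -0.56 ± 0.14 (SE), with 41 not past the test and none past it when adjusted over the list alone (camera adjusted p = 0.834). None of 6 proteasome genes (adjusted p = 0.834 by camera) and none of 5 histone genes (0.819) passed over all genes or when adjusted over the list alone, and upper-quartile scaling called 1 proteasome gene lower. Apart from these housekeeping lists, 3 photoreceptor and photolyase genes were tested. Of them the photolyase gene phr1 rose by 1.13 ± 0.27, also when adjusted over the list alone, and was chosen for naming after its values were seen. Its call (adjusted p = 0.0226 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.0636, 0.0689 and 0.0666) or mutant replicate 2 (0.0597).

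The authors' deposited table lists 2368 genes at an adjusted p below 0.05, 1222 higher and 1146 lower in the mutant, of which 184 and 344 were at least 2-fold changed. Of these genes 2324 (98.1%) were also called here, all in the same direction. The exact 95% interval of 97.5 to 98.6% treats genes as independent, which they are not, and both sets of calls come from the same counts. Across 8187 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the fit correlated at r = 0.999, both having been computed from the same counts. A further 1438 genes were called here alone. For 1050 of them the authors' deposited table gives an adjusted p of 1, and the most abundant of these had a mean of 17.5 CPM, whereas the least abundant gene called in that table had 16.2 CPM. Genes named by the rule that are among these 1050, and so not called in that table, were hfb1, man5a, chit18-11, TRIREDRAFT_72632, TRIREDRAFT_73256, TRIREDRAFT_56278 and TRIREDRAFT_58366.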

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

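All alternatives here were planned except the fit without the 2 most abundant protein IDs, which was chosen after the result was seen. The count of 3762 genes changed stayed within 1.5 times under every alternative but 1, at 3067 to 3655 without single libraries, 3631 with DESeq2 and 3740 without the 2 IDs. The exception was scaling by library totals alone, with 2018 genes, 400 of them higher and 214 at least 2-fold higher. By construction it counts the excess of the 2 IDs against all other genes. No label says that a replicate number marks a shared culture or time, and a pairing was neither established nor excluded: deviations of same-numbered libraries correlated at 0.17, 0.035 and 0.11, 5 of 6 libraries correlated best with their own number, and a replicate block gave 3942 genes. Of the lists, the call of the hemicellulases ended with an estimated correlation, which gave a camera adjusted p of 0.999 for every list. Without single libraries the adjusted p of the cellulases ranged from 0.00375 to 0.151. Fry, a different question, called hemicellulases (0.0142), chitinases (0.0132), glycolysis (0.0142), folding and secretion (0.0472) and small GTPases (0.00197). Lists that were not called turned direction in some fits, with no cause tested: beta-glucosidases with fry (0.614) and without wild-type replicate 1 (0.881) or 3 (0.99) or mutant replicate 3 (0.962), ribosomal proteins with library totals (0.96) and without wild-type replicate 2 (0.924) or mutant replicate 3 (0.707), proteasome with library totals (0.988), citrate metabolism without mutant replicate 3 (0.962), and the MAP kinase list with library totals (0.97), the replicate block (0.98) and without wild-type (0.956) or mutant replicate 1 (0.896). Over all fits without single libraries, turned or not, adjusted p ranged from 0.881 to 0.99 (beta-glucosidases), 0.403 to 0.924 (ribosomal), 0.833 to 0.962 (citrate) and 0.887 to 0.99 (MAP kinase). DESeq2 called 98.7% of the genes called in the authors' deposited table. Of 72 genes past the threshold that were selected for naming, 16 lost the call with library totals alone (4 of them falls that grew, with larger SE) and 11 without some single library. TRIREDRAFT_26163, not called, turned to -0.223 with library totals and ranged from -0.055 to 0.154 without single libraries. Of simulated 2-fold changes 81.1% were recovered below the median of 35.3 CPM and 100% above it, a division chosen afterwards.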

Other observations

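The tests of the fixed ratio, of the strain difference, of run genes against the share of cre1 and of reads carried over, and the genes named here, were chosen after the results were seen. Of 63 tested genes with a symbol that stood in no list, 12 rose and 17 fell. The thiamine biosynthesis genes thi4 and nmt1 fell together, from 887 ± 21.5 to 371 ± 41.3 and from 496 ± 52.4 to 201 ± 27.3 CPM (mean ± SD, n = 3), by 1.26 ± 0.10 and 1.31 ± 0.12 (SE) on the log2 scale. The gene ino1, named for inositol-phosphate synthase, fell by 0.97 ± 0.11, and hxt1, named for a hexose transporter, rose by 0.88 ± 0.10, from 431 ± 27.1 to 794 ± 62.4 CPM. Adjusted p-values of these 4 genes lay between 2.65e-07 and 6.26e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

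Some genes differed within a strain. TRIREDRAFT_66551 was at 54.8, 18.8 and 21.1 CPM in wild-type replicates 1, 2 and 3 and at 0.775, 0.929 and 1.15 CPM in the mutant libraries. Among genes with a mean of at least 5 CPM in 1 strain, 12 were at least 2-fold higher in wild-type replicate 1 than in both other wild-type libraries, 19 were at least 2-fold higher in mutant replicate 3 than in both other mutant libraries, and 39 were at least 2-fold lower in mutant replicate 1 than in both other mutant libraries.

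The 6 libraries can be split into 3 and 3 in 10 ways, 1 of which is the real one, and this is too few for a share under 0.05. The real split gave 3762 genes and the highest of the other splits 0 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the other splits gave at most 153 genes at an unadjusted p below 0.05.

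Protein IDs 48266 and 61593 took 37.8% of the counts of mutant replicate 2, against 2.7 to 11.1% in the other libraries. With TMM scaling in both fits, 3740 genes were called without these IDs and 3762 with them, 3712 being called in both fits in the same direction. Under TMM the calls of other genes thus hardly depended on these IDs. As TMM trims genes with extreme ratios, such a result was likely beforehand. It does not settle how the excess of the IDs should be counted, and library totals alone gave 2018 genes. A single transcript source read in a fixed ratio is argued against, because the ratio of their counts differed 2.23 times between the highest and the lowest library. A difference between the strains cannot be told apart from the spread of the mutant libraries, as ID 48266 was higher by 3.04 ± 1.03 (SE) on the log2 scale with an adjusted p of 0.0726 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and by 1.59 with an adjusted p of 0.00634 without mutant replicate 2. In the same test ID 61593 was higher by 2.28 ± 0.99 (adjusted p = 0.139), and by 0.74 (0.0238) without mutant replicate 2. For both IDs all 3 mutant libraries lay above all 3 wild-type libraries. Which transcripts the IDs stand for was not tested, as no sequences were used here.

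Genes that fell at least 2-fold lay next to each other in 171 pairs, against a mean of 65.1 and a highest value of 94 in 10000 shuffles among genes of like expression. Chance arrangement of genes with like expression is argued against by the share of shuffles as high, 0.0001, the smallest they can give; genes that rose made 46 pairs against a mean of 11.8. The 34 runs of 3 or more falling neighbours held 122 genes, of which 1.6% had no count in all 3 mutant libraries. As cre1, itself deleted, kept counts too, this percentage does not decide whether a stretch of the genome was deleted. A deleted stretch in the mutant is argued against as the whole cause of the runs by another comparison. Of the run genes 54.9% lay clearly above the share that cre1 kept, which was at most 13.7% of the wild type. For the other 55 genes, of which 3.6% had no mutant count, a deletion cannot be told apart from a fall. For cre1 kept counts too and no genome sequence was used. Counted by run, 8 of the 34 runs had all genes clearly above that share and 5 had none. A deletion spanning a whole run would thus have to lie in those 5, unless its genes kept larger shares than cre1. Reads shared between similar neighbours were not tested, and shared regulation of neighbouring genes that depends on cre1 may be a candidate explanation, likewise untested.

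The mutant libraries kept cre1 counts at 10.5% of the wild-type mean. If wild-type RNA or reads carried into the mutant libraries were the whole source, no abundant wild-type transcript could lie clearly below the share of cre1. Of 2056 genes with at least 100 CPM in the wild type, 8 did, among them TRIREDRAFT_21876 at 0.4%, TRIREDRAFT_104251 at 1.46% and TRIREDRAFT_52206 at 6.57% of the wild type. Reads from a part of cre1 left in the mutant genome may be a source of the counts and were not tested.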
